A study of Rattus norvegicus with 28 samples.

How the data were processed

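RNA was measured in prefrontal cortex of adult male Sprague-Dawley rats, an outbred laboratory stock. Per the labels, each animal had an injection of ketanserin or of its Tween vehicle, then an injection of psilocybin or of saline, and tissue was taken 24 h later. The 28 libraries form 7 groups of 4 biological replicates. These are vehicle, psilocybin alone at 1 or 3 mg/kg, ketanserin alone at 1 or 3 mg/kg, and ketanserin with psilocybin at 1 mg/kg of each or at 3 mg/kg of each. Per the labels' protocols, poly-A RNA was made into strand-marked libraries by the dUTP method. Replicate numbers here only name libraries, since the labels number none, and they pair nothing across groups.

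The deposited table holds raw counts of reads per gene for 36387 annotated genes and assembled transcripts, per the file headers. Per the submitters' processing notes, the tools were HISAT2 2.0.5, StringTie 1.3.3b and featureCounts 1.5.0-p3 and the rat genome build was rn6. The notes give the tools no roles, and the strand setting of the counting is not given in the sources used here. Reads of overlapping, antisense or near-identical genes can therefore have been divided or lost, which affects symbols with more than 1 gene record (Faah, Phyhip, Rpl35a, Rpl7a, Gorasp2) and the adjacent pairs Nhp2 with Rmnd5b and Dcun1d2 with Adprhl1. The authors also deposited FPKM values per gene. They were only checked against the counts, and the library size that they imply was 0.915 to 1.07 times the total count. All coordinates are those of the deposited table on rn6, and no genome sequence was used here.

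The 3842 assembled transcripts with no gene name took 1.99 to 4.46% of the counts of a library. They were kept in the library totals and in the tests, since each is a located transcript, and were left out when genes were named. Total counts per library were 12783067 to 18538414, with a median of 15366978.

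Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by group, which left 17404, and libraries were scaled by TMM factors. A negative binomial model with 1 coefficient per group was fitted to all 28 libraries, so that the groups shared 1 estimate of the spread with 21 residual degrees of freedom. Contrasts were tested with the robust quasi-likelihood F test, which is two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the tested genes. A gene was called at an adjusted p under 0.05. Standard errors and 95% intervals of log2 fold changes come from the same fit. For the 15477 genes with a mean log2 CPM of at least 0, the median half-width of the 95% interval was near 0.438 log2 units in pairwise comparisons, 0.620 in interactions and 0.380 when both doses were pooled. These widths hold the spread between animals as well as the counting error that depth sets. Levels are CPM, the counts of a gene relative to the library total scaled by its TMM factor, as mean ± SD over 4 libraries.

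On simulated counts with the means and library sizes of these data and 200 changed genes, edgeR recovered 18.2% of genes changed 1.5-fold, 43.9% at 2-fold and 84.6% at 4-fold for psilocybin at 3 mg/kg against vehicle, with 4 false calls among 16947 unchanged genes. Ketanserin at 3 mg/kg gave 16.9%, 45.5% and 78.5%, with 3 false calls. DESeq2 made 15 and 21 on 17174 and 17172 genes. Random splits of the real libraries gave edgeR up to 6192 and 1 calls in these comparisons, so real rates may differ. Group names carry no meaning in such splits, so that gap is no difference between the drugs.

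There were 18 comparisons. Each treated group was set against vehicle, each combination against psilocybin alone and against ketanserin alone, and the doses against each other. The interaction at each dose (combination minus psilocybin alone minus ketanserin alone plus vehicle), both doses pooled against vehicle, and any difference among the 7 groups were also tested.

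Gene lists were tested with camera in limma 3.58.1 on voom log2 CPM, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 27 lists within a comparison. The lists were serotonin receptors, other ketanserin targets, immediate early genes, late activity and neurotrophin genes, glutamate receptors, synaptic structure genes, GABA signalling genes, interneuron markers, upper layer and deep layer neuron markers, circadian clock genes, glucocorticoid response genes, myelin and mature oligodendrocyte genes, oligodendrocyte precursor markers, astrocyte markers, microglia markers, endothelial and mural markers, choroid plexus and ependyma markers, striatum markers, olfactory bulb markers, meninges and fibroblast markers, blood genes, heat shock and chaperone genes, innate immune and interferon genes, perineuronal net and matrix genes, ribosomal protein genes and nuclear genes of mitochondrial respiration. Camera with an estimated correlation and the rotation test fry were run beside it. Fry asks whether the genes of a list move, on balance, one way, and compares them with no other genes. A list score is the mean over its members of log2 CPM centred on the mean over all libraries, and scores were compared by two-sided exact permutation tests.

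Groups, comparisons, tests, lists and alternatives were fixed before the data were examined. So was the rule for naming genes. In each main comparison up to 8 called genes per direction were to be named, and where fewer than 3 passed in a direction the 3 with the smallest raw p were named instead. In secondary comparisons the limit was 4, or 8 for the test among all groups. Up to 4 members with the smallest raw p were named for each list described, and Htr2a and Htr2c in every comparison. Genes needed a mean log2 CPM of at least 0 and a symbol, and names that are clone accessions were not taken as symbols. Values of 4 genes that the rule named are not reported here.

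The alternatives were DESeq2 1.42.0, RLE size factors, no low-count filter, a fit of only the groups compared, surrogate variables from sva 3.50.0 as covariates (2 were found), and leaving out each library in turn. List tests without 1 library that stood apart (replicate 4 of the 3 mg/kg combination or, in the score of a called list, replicate 1 of psilocybin at 3 mg/kg, 4 of ketanserin at 1 mg/kg or 3 of ketanserin at 3 mg/kg), and the gene tests without the first of these in comparisons that do not hold it, were added after the data had been examined.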

Results

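Transcripts were counted in prefrontal cortex of 28 adult male rats 24 h after drug injection, with 4 animals in each of 7 groups. Psilocybin is converted in the body to psilocin, an agonist of serotonin receptors, and ketanserin blocks the serotonin 2A receptor through which many acute effects of psilocin run. The groups address which transcripts differ on the day after each drug and whether ketanserin given before psilocybin alters that response. Mitochondrial transcripts took 6.98 to 11.6% of the counts of a library. No library was a copy of another, since the chi-square per gene between libraries was 6.19 to 178.

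The groups overlapped on the leading 2 principal components, which carried 27.5% and 12.1% of the variance. Replicate 4 of the group given ketanserin and psilocybin at 3 mg/kg each lay far from the other 27 libraries, at -133 on PC1 and 91.6 on PC2 against -38.3 to 72.0 and -27.0 to 41.4. In that library 19602 annotated genes and transcripts had a count of 0, against 15344 to 16657 in the others, and unnamed transcripts took 4.46% of the counts against 1.99 to 2.53%. Its median correlation with the other libraries was 0.90, against 0.951 to 0.974. This distant library was kept in all comparisons.

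**Figure D1:**
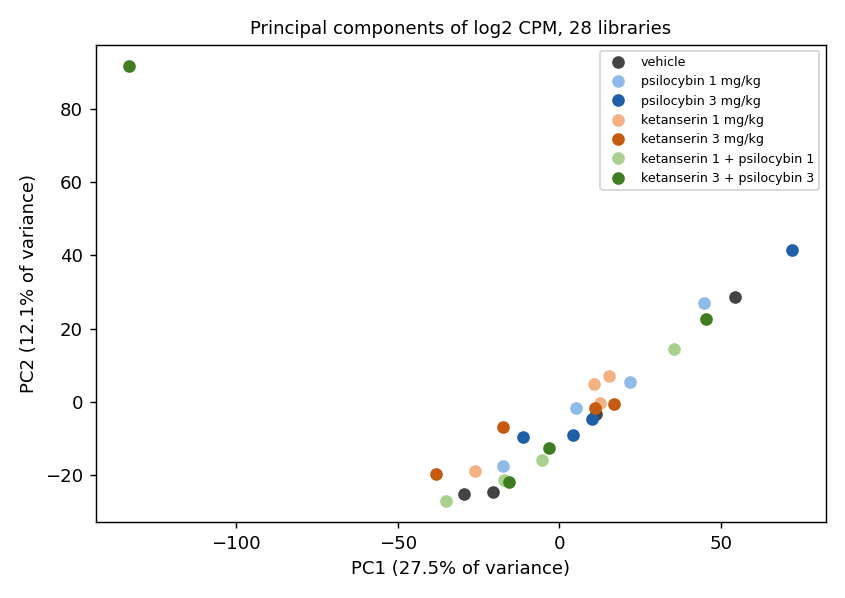
Principal components of log2 CPM, with PC1 (27.5% of variance) on the x axis and PC2 (12.1%) on the y axis, each point 1 library coloured by group. The distant library sits at -133 and 91.6, and the 7 groups overlap in the other 27.

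Htr2a, which encodes the serotonin 2A receptor (ENSRNOG00000010063, chromosome 15, 56666012 to 56735382 on rn6), was at 34.0 ± 3.58 CPM in vehicle (SD, n = 4) and between 29.4 ± 3.12 and 34.3 ± 2.81 CPM in the treated groups. Its log2 fold change against vehicle was -0.21 (95% interval -0.54 to 0.13) after psilocybin at 1 mg/kg and 0.01 (-0.32 to 0.34) at 3 mg/kg. It was 0.00 and 0.01 after ketanserin at 1 and 3 mg/kg, and -0.07 and -0.14 after the combinations at 1 and 3 mg/kg. Htr2c, the related serotonin 2C receptor (ENSRNOG00000030877, chromosome X, 118084890 to 118318039), was at 14.9 ± 5.12 CPM in vehicle and 15.4 ± 2.38 to 20.8 ± 2.51 CPM elsewhere. Its log2 fold change was 0.48 (SE 0.251) and 0.39 (SE 0.251) after psilocybin, 0.06 and 0.48 after ketanserin, and 0.46 and 0.14 after the combinations at 1 and 3 mg/kg. Against psilocybin alone the combinations differed by 0.14 and -0.15 for Htr2a and by -0.03 and -0.24 for Htr2c at 1 and 3 mg/kg. Against ketanserin alone they differed by -0.07 and -0.15 for Htr2a and by 0.40 and -0.33 for Htr2c. The interactions were 0.14 and -0.16 for Htr2a and -0.08 and -0.72 (95% interval -1.45 to 0.01) for Htr2c. The higher dose minus the lower gave 0.22 and 0.01 for Htr2a and -0.10 and 0.42 for Htr2c with psilocybin and ketanserin. Pooled doses against vehicle gave -0.10, 0.00 and -0.10 for Htr2a and 0.44, 0.27 and 0.30 for Htr2c with psilocybin, ketanserin and both drugs. None of these differences passed the edgeR test (adjusted p of 0.730 to 1.00).

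After psilocybin at 1 mg/kg, Mrpl36, a mitochondrial ribosomal protein (ENSRNOG00000047971, chromosome 1, 32570296 to 32570589), was at 5.93 ± 3.20 CPM against 0.466 ± 0.340 in vehicle (SD, n = 4). The log2 fold change was 3.65 (SE 0.824). Rmnd5b, a subunit of an E3 ubiquitin ligase complex (ENSRNOG00000047396, chromosome 10, 34979923 to 34990943), was at 8.49 ± 3.26 against 0.446 ± 0.121 CPM (4.23, SE 1.06). RragB, a Rag GTPase of amino acid sensing, differed by 1.68. In the other direction lay Pla2g4e, a cytosolic phospholipase, at 17.4 ± 1.05 against 25.1 ± 3.11 CPM (-0.53, SE 0.112). Also lower were Sh2b3, an adaptor that restrains cytokine signalling (-0.50), and Gmeb1, a glucocorticoid modulatory element binding protein (-0.40). None passed. edgeR called 0 of 17404 genes, with 289 at an unadjusted p under 0.05. Of 100 library splits 73 reached that count (24 to 90 over 18 comparisons). DESeq2 called 3 genes, Pla2g4e, Rmnd5b and Mrpl36, and a fit of only these groups 1, Rmnd5b.

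Immediate early genes, which neuronal activity switches on, were higher as a list after psilocybin at 1 mg/kg, with 25 of 30 members above vehicle and a median log2 fold change of 0.20 (camera adjusted p = 0.000781; adjusted p = 0.864 with an estimated correlation). Members named by p were Fosb (0.65; 0.39 without replicate 2), Egr1 (0.30), Nr4a2 (0.36; 0.15 without it, 0.16 without vehicle replicate 4) and Klf10 (-0.32; -0.18 without vehicle replicate 3). Myelin and mature oligodendrocyte genes were higher in 16 of 18 members (median 0.18, adjusted p = 0.0240), led by Ermn (0.59; 0.37 without replicate 3), Ugt8 (0.31; 0.04 without it, up to 0.52 without vehicle replicate 2) and Cldn11 (0.29). Heat shock and chaperone genes were higher in 12 of 14 (0.11, adjusted p = 0.00196), with Creld2 at 0.26 and Sdf2l1 at 0.29. Both lists had an adjusted p of 0.864 with an estimated correlation. Ribosomal protein genes were higher in 71 of 82 members (0.09) and nuclear genes of mitochondrial respiration in 72 of 82 (0.10), each at an adjusted p of 0.00196 and of 0.887 with an estimated correlation. Members were Rpl32 at 0.63 (0.40 without replicate 2), Uqcrc1 at 0.17 and Atp5a1 at 0.08. In each called list of this and the later comparisons 0 members passed over all genes, and 0 passed adjusted over the list alone unless named. With surrogate variables as covariates the myelin, ribosomal and mitochondrial calls were lost (adjusted p of 0.349 to 0.748).

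After psilocybin at 3 mg/kg, C2cd4c, a C2 domain protein, was at 47.2 ± 2.69 CPM against 32.2 ± 2.10 in vehicle (SD, n = 4), a log2 fold change of 0.55 (SE 0.128). RragB was at 6.38 ± 3.03 against 1.60 ± 0.539 (1.99, SE 0.481). Grcc10 (ENSRNOG00000025810, chromosome 4, 157264383 to 157266018) had a log2 fold change of 5.41 (SE 1.22) that was 0.38 without replicate 4, at 75.4 CPM where the other 3 libraries were at 0.0694 to 0.995. Syt12, a synaptotagmin of the synaptic vesicle, was at 65.1 ± 0.672 against 81.7 ± 5.86 CPM (-0.33, SE 0.0801). Epcam, an epithelial adhesion molecule, was at 0.406 ± 0.159 against 1.64 ± 0.187 (-1.98, SE 0.532), and Il17ra, a receptor for interleukin 17, at 29.9 ± 3.59 against 43.2 ± 2.57 (-0.53, SE 0.146). None of the 6 passed. edgeR called 0 genes, 523 had an unadjusted p under 0.05, DESeq2 called 0, and a fit of only these groups called 1. It was Fam111a, a protease gene at 14.1 to 30.8 CPM in this group and 0.203 to 0.744 in vehicle, and 1 of 33 genes that sat at 2 levels between animals.

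Myelin and mature oligodendrocyte genes were lower after psilocybin at 3 mg/kg in 18 of 18 members, with a median log2 fold change of -0.38 (camera adjusted p = 8.92e-07; adjusted p = 0.763 with an estimated correlation). Ugt8, an enzyme of myelin lipid synthesis, was at -0.61 (-0.40 without vehicle replicate 2), the gap junction gene Gjb1 at -0.76, Mobp at -0.66 (-1.16 without replicate 4) and Enpp2 at -0.30. Immediate early genes were higher in 19 of 30 (0.19, adjusted p = 0.00760), with Junb (0.67), Fosb (0.65), Nr4a1 (0.37) and Arc (0.77; 1.23 without vehicle replicate 3). Blood genes were higher in 6 of 6 (0.31, adjusted p = 0.0253), with Hbb at 0.34 (0.10 without replicate 2, 0.71 without vehicle replicate 2) and Slc4a1 at 0.46 (0.26 and 0.83 without vehicle replicates 4 and 2). Ribosomal protein genes were higher in 72 of 82 (0.25, adjusted p = 2.46e-11) and respiration genes in 74 of 82 (0.16, adjusted p = 0.000282), with Rpl30 at 0.94, Rpl19 at 0.30 and Uqcrc2 at -0.15. With an estimated correlation the adjusted p was 0.763 for the immediate early, blood and ribosomal lists and 0.907 for respiration. The ribosomal list score was 0.693 in replicate 1 against 0.0434 to 0.119 in the other 3 libraries of this group. Replicate 1 also had the lowest TMM factor of the 28 libraries (0.904), the highest PC1 (72.0) and the lowest Spearman rho across genes of deviation with gene length (-0.323; up to 0.283 in others). Without replicate 1 the immediate early, blood and respiration lists were not called (adjusted p = 0.155, 0.0559 and 0.845), the ribosomal median was 0.06 (0.0498), and the respiration median turned to -0.04. Surrogate variables ended the blood and respiration calls (adjusted p = 0.0861 and 0.820).

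Ketanserin at 1 mg/kg was accompanied by a higher level of LOC100911575, a locus with a provisional name (ENSRNOG00000037607, chromosome 1, 214428526 to 214430515), at 43.2 ± 11.6 CPM against 3.12 ± 0.835 in vehicle (SD, n = 4). All 4 libraries lay at 26.6 CPM or more and all vehicle libraries at 4.12 or less, and the log2 fold change of 3.79 (SE 0.645) had an adjusted p of 0.0828. Dusp6, a phosphatase of ERK that neuronal activity induces, was at 30.8 ± 6.45 against 22.2 ± 3.68 CPM (0.47, SE 0.136), and Phyhip at 46.6 ± 43.8 against 7.25 ± 2.42 (2.68, SE 0.727). Pip5kl1, a lipid kinase family member, was lower (-1.21, SE 0.326). Map7, a microtubule-associated protein, was at 42.9 ± 3.41 against 58.2 ± 3.62 (-0.44), and Serhl2, a serine hydrolase, at 1.67 ± 0.349 against 3.59 ± 0.468 (-1.10). The edgeR test passed 0 genes, with 360 at an unadjusted p under 0.05. DESeq2 called 1 gene, LOC100911575, and a fit of only these groups 2, LOC100911575 and Rtkn.

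The immediate early list was higher after ketanserin at 1 mg/kg in 24 of 30 members (median 0.21, camera adjusted p = 9.71e-10; adjusted p = 0.109 with an estimated correlation), with Dusp6 (0.47), Egr4 (0.65), Junb (0.68) and Fosb (0.64). Myelin genes were lower in 18 of 18 (-0.33, adjusted p = 0.00592; 0.856 as the adjusted p with an estimated correlation), with Cnp at -0.35 and Cldn11 at -0.40 (-0.08 and -0.10 without vehicle replicate 2). Markers of meninges and fibroblasts were lower in 11 of 13 (-0.25, adjusted p = 0.0107), with the collagen genes Col3a1 at -0.71 and Col1a1 at -0.35 (-0.17 without replicate 2). Synaptic structure genes were called higher (adjusted p = 0.0146) although 14 members were above and 15 below vehicle, with a median of -1.7e-05 and a mean of 0.0054. Nlgn2 (0.22), Dlg4 (0.23), Nrxn2 (0.23) and Syp (0.20) led. Both of these lists had an adjusted p of 0.751 with an estimated correlation. Without replicate 4, whose ribosomal and respiration scores stood apart (-0.331 and -0.352), the synaptic list was not called (0.525) and had a mean of -0.18.

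After ketanserin at 3 mg/kg, 1 record of Faah, the hydrolase that breaks down the endocannabinoid anandamide (ENSRNOG00000045949, chromosome 5, 134852875 to 134871775), was at 1.47 ± 0.147 CPM against 22.2 ± 4.44 in vehicle (SD, n = 4), a log2 fold change of -3.91 (SE 0.823). Faah has another record, so reads shared by the records are uncertain, and both records were among the 33 genes at 2 levels between animals. Slfn13, a Schlafen family gene, was at 1.66 ± 0.517 against 3.47 ± 0.949 CPM (-1.07), and Ccdc78, a gene of centriole assembly, at 0.477 ± 0.415 against 1.65 ± 0.146 (-1.77). Rmnd5b (3.56, SE 1.05), C2cd4c (0.43, SE 0.128) and Dusp6 (0.45, SE 0.136) were the highest by p, with Dusp6 at 30.4 ± 2.63 and C2cd4c at 43.3 ± 8.05 CPM. These differences did not pass in edgeR, which called 0 genes (348 at an unadjusted p under 0.05). DESeq2 and a fit of only these groups each called 1 gene, Faah.

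After ketanserin at 3 mg/kg, the immediate early list was higher in 23 of 30 members (median 0.21, camera adjusted p = 1.86e-05) and late activity and neurotrophin genes in 17 of 19 (0.14, adjusted p = 0.00208), both at an adjusted p of 0.341 with an estimated correlation. Glutamate receptors were higher in 16 of 22 (0.07, adjusted p = 0.0246) and deep layer neuron markers in 10 of 13 (0.17, adjusted p = 0.00290), both at an adjusted p of 0.411 with an estimated correlation. Synaptic structure genes were higher in 20 of 29 (0.05, adjusted p = 0.00369; adjusted p = 0.512 with an estimated correlation). Named members were Csrnp1 (0.66), Fosb (0.74), Ptgs2 (0.26), Nptx1 (0.21), Grm8 (0.34), Ntsr1 (1.15), Syt6 (0.36) and Nlgn2 (0.20), with Fosb at 0.36 and Ntsr1 at 0.70 without replicate 2. Meninges and fibroblast markers were lower in 13 of 13 (-0.27, adjusted p = 0.00904; adjusted p = 0.588 with an estimated correlation), with Col3a1 at -0.59 and Lum at -0.37 (-0.20 without replicate 2, -0.19 without vehicle replicate 1). Ribosomal protein genes were lower in 71 members and higher in 10 (-0.20, adjusted p = 1.86e-05), with Rpl17 at -0.87 (-0.44 without vehicle replicate 2). Respiration genes were lower in 73 of 82 (-0.17, adjusted p = 2.29e-05), with Ndufaf6 at -0.57. Both lists had an adjusted p of 0.823 with an estimated correlation. The deep layer score was -0.104 in replicate 3 against 0.206 to 0.225 in the other 3 libraries. Without replicate 3 the glutamate receptor, synaptic, ribosomal and respiration calls were lost (adjusted p of 0.0749 to 0.246), and surrogate variables ended the glutamate receptor call (0.0570).

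With ketanserin and psilocybin at 1 mg/kg each, LOC100911575 was at 32.7 ± 20.7 CPM (SD, n = 4; 1 library at 4.17) against 3.12 ± 0.835 in vehicle, a log2 fold change of 3.39 (SE 0.637, adjusted p = 0.325). Rmnd5b was at 6.98 ± 3.48 against 0.446 ± 0.121 CPM (3.95, SE 1.06) and Dusp6 at 31.2 ± 3.66 against 22.2 ± 3.68 (0.49, SE 0.136). Tsr2, a ribosome maturation factor, was at 10.8 ± 1.17 against 18.3 ± 0.856 CPM (-0.77, SE 0.181). Ubap1l was at 1.84 ± 0.176 against 3.48 ± 1.07 (-0.92), and Slc12a9, of the cation chloride cotransporter family, at 19.2 ± 2.30 against 26.1 ± 4.58 (-0.45). None passed. Against vehicle edgeR called 0 genes, and 227 had an unadjusted p under 0.05. DESeq2 called 1, LOC100911575, and a fit of only these groups 2, Rmnd5b and Ndufa1. Without replicate 3 of the combination LOC100911575 was called (adjusted p = 0.0104).

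The immediate early list was higher in this combination in 22 of 30 members (median 0.26, camera adjusted p = 2.17e-08; adjusted p = 0.189 with an estimated correlation), with Junb (0.68), Arc (1.19) and Nr4a1 (0.52), and 1 member, Dusp6, passed adjusted over the list alone. Deep layer neuron markers were higher in 11 of 13 (0.15, adjusted p = 0.0144; adjusted p = 0.782 with an estimated correlation), with Syt6 at 0.42 and Foxp2 at 0.49 (0.30 and 0.78 without vehicle replicates 1 and 2). Ribosomal protein genes were lower in 65 of 82 (-0.12, adjusted p = 0.0133) and respiration genes in 71 of 82 (-0.11, adjusted p = 0.0413), with Atp5sl at -0.17. Both had an adjusted p of 0.960 with an estimated correlation. With surrogate variables both were at 0.989 and the means turned, to 0.03 for ribosomal and 0.08 for respiration genes.

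With both drugs at 3 mg/kg, LOC100911575 rose to 59.6 ± 18.6 CPM from 3.12 ± 0.835 in vehicle (SD, n = 4), with all 4 libraries at 46.9 to 87.3 CPM and the vehicle libraries at 2.10 to 4.12. The log2 fold change was 4.25 (SE 0.655, 95% interval 2.90 to 5.60), and the edgeR adjusted p was 0.0183. Dcun1d2, a factor of cullin neddylation, was at 4.97 ± 2.17 against 0.326 ± 0.455 CPM (3.89, SE 0.958). Kat2b, a histone acetyltransferase, was at 1.86 ± 0.423 against 3.82 ± 0.359 CPM (-1.02, SE 0.240). Ptk7, a receptor of planar cell polarity, was at 8.62 ± 2.15 against 13.5 ± 2.20 (-0.64) and Yars2, a mitochondrial tRNA synthetase, at 13.1 ± 2.42 against 18.5 ± 3.61 (-0.50). These 4 did not pass. LOC100911575 was the only gene called by edgeR and DESeq2 among 17404 and by a fit of only these groups among 16085, and 544 genes had an unadjusted p under 0.05. The call was lost when any 1 vehicle library was left out (adjusted p of 0.108 to 0.235), without replicate 2 of the combination (0.0773), without a low-count filter (0.0849) and with surrogate variables (0.133). The log2 fold change was then 4.01 to 4.42.

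**Figure D2:**
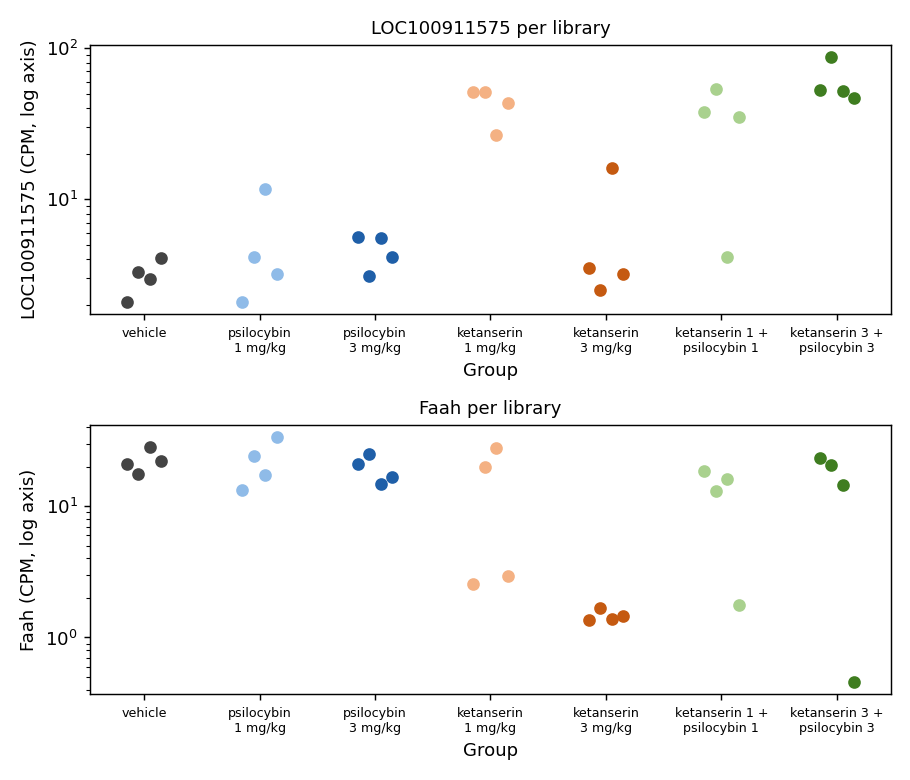
LOC100911575 (upper panel) and Faah record ENSRNOG00000045949 (lower panel) in CPM on log y axes, by treatment group on the x axis, with 1 point per library. LOC100911575 lies at 2.10 to 4.12 CPM in vehicle and at 46.9 to 87.3 CPM after both drugs at 3 mg/kg, and Faah at 17.6 to 28.2 CPM in vehicle and 1.37 to 1.68 CPM after ketanserin at 3 mg/kg.

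Immediate early genes were higher in the 3 mg/kg combination in 23 of 30 members (median 0.14, camera adjusted p = 0.0363), with Arc at 1.09, Junb at 0.53 (0.34 without replicate 2), Fosb at 0.56 (0.34 without replicate 3) and Jun at -0.27. Blood genes were higher in 5 of 6 (0.25, adjusted p = 0.0198), with Slc4a1 at 1.02 and Alas2 at 0.89 (0.41 and 0.43 without the distant library). Both lists had an adjusted p of 0.721 with an estimated correlation. Respiration genes were lower in 72 of 82 members (-0.12, adjusted p = 0.0435; adjusted p = 0.866 with an estimated correlation), with Ndufs1 at -0.14 and Cox7a2 at -0.66 (-0.37 without the distant library). Surrogate variables ended these 3 calls (adjusted p of 0.0603 to 0.382). Without the distant library the respiration list was not called (adjusted p = 0.202) and its mean fold change turned to 0.09.

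Set against psilocybin alone at 1 mg/kg, the combination had a lower level of C1ql2, a secreted protein of synapses (ENSRNOG00000046863, chromosome 13, 36378356 to 36380302), at 2.21 ± 0.491 against 11.6 ± 7.66 CPM (SD, n = 4; log2 fold change -2.39, SE 0.427, adjusted p = 0.130). Sdc1, a heparan sulfate proteoglycan, was at 1.19 ± 0.271 against 4.16 ± 2.04 CPM (-1.79) and Frs3, an adaptor of growth factor receptors, at 22.3 ± 2.47 against 31.4 ± 2.79 (-0.50). LOC100911575 (2.63, SE 0.608), Il6r, the interleukin 6 receptor (0.76), and Far2, a fatty acyl reductase (0.46), were higher, at 32.7 ± 20.7, 10.6 ± 1.52 and 62.8 ± 6.01 CPM against 5.28 ± 4.37, 6.25 ± 0.726 and 45.5 ± 3.28. None passed. edgeR called 0 genes, with 718 at an unadjusted p under 0.05. DESeq2 called 1 (C1ql2) and a fit of only these groups 0. Without replicate 1 of psilocybin alone, where C1ql2 was at 1.77 CPM, C1ql2 was called (adjusted p = 4.62e-05).

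Relative to psilocybin alone at 1 mg/kg, heat shock genes were lower in 13 of 14 members (median -0.18, camera adjusted p = 0.000176), with Sdf2l1 at -0.58 and Creld2 at -0.41. Meninges and fibroblast markers were lower in 11 of 13 (-0.40, adjusted p = 0.00450), with Igf2 at -0.77 (-0.42 without replicate 4 of psilocybin alone). Upper layer neuron markers were higher in 9 of 10 (0.23, adjusted p = 0.0367), with Cux2 at 0.45 (0.27 without replicate 2 of psilocybin alone). Ribosomal protein genes were lower in 76 of 82 (-0.21, adjusted p = 1.79e-06) and respiration genes in 72 of 82 (-0.22, adjusted p = 1.57e-05), with Rpl14 at -0.29 and Uqcrc1 at -0.27. With an estimated correlation the adjusted p was 0.642 for respiration and 0.587 for the other 4 lists. The upper layer, ribosomal and respiration calls were lost with surrogate variables (adjusted p of 0.302 to 0.693).

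Set against psilocybin alone at 3 mg/kg, the combination had more LOC100911575, at 59.6 ± 18.6 against 4.61 ± 1.21 CPM (SD, n = 4; log2 fold change 3.70, SE 0.633, adjusted p = 0.0896). Epcam (2.14) and Tsc22d4 (2.32) were also higher, at 1.24 and 1.23 without the distant library, which held their highest values. Grcc10 (-6.51, SE 1.33) was lower through the 1 psilocybin library at 75.4 CPM (-1.48 without it). Wnt5b, a Wnt ligand, was at 3.04 ± 0.839 against 5.56 ± 1.60 CPM (-0.86), and RGD1562726 at 0.751 ± 0.268 against 2.18 ± 0.316 (-1.52). The edgeR test called 0 genes, and 999 had an unadjusted p under 0.05, where chance alone would give 870. DESeq2 and a fit of only these groups each called 1, LOC100911575. Without replicate 3 of psilocybin alone Grcc10 was called (adjusted p = 0.0471).

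Ribosomal protein genes and respiration genes were each lower than after psilocybin alone at 3 mg/kg in 77 of 82 members, with medians of -0.29 (camera adjusted p = 2.59e-08 and 2.33e-07), including Rpl4 at -0.22, Ndufa2 at -0.40 and Ndufb6 at -0.43. Microglia markers were lower in 11 of 15 (-0.25, adjusted p = 0.0388), with C1qa at -0.49 and Aif1 at -0.53. Synaptic structure genes were higher in 22 of 29 (0.12, adjusted p = 0.0387), with Bsn at 0.43 and Shank1 at 0.42, and myelin genes in 14 of 18 (0.17, adjusted p = 0.0474), with Mobp at 0.65 (1.15 without replicate 4 of psilocybin alone). The adjusted p with an estimated correlation was 0.833 for myelin and 0.726 for the other 4. Without the distant library, in which Shank1 was at 3385 CPM against 1287 to 1352 in the other 3, the synaptic, myelin and microglia lists were not called (adjusted p of 0.0908 to 0.785), Shank1 was at -0.06, Bsn at 0.16, Aif1 at -0.27, Ndufa2 at -0.21 and Ndufb6 at -0.20, and the ribosomal and respiration medians were -0.19 and -0.11 (5.57e-06 and 0.0460). None of the 5 was called (0.0605 to 0.190) without replicate 1 of psilocybin alone, which stood apart in its group in the ribosomal score (0.693), Ndufa2 (115 CPM) and Ndufb6 (140 CPM). Ribosomal and respiration medians were then -0.09 and -0.07, Ndufa2 -0.17, Ndufb6 -0.21, C1qa -0.29 and Aif1 -0.31. With surrogate variables the synaptic, microglia and respiration lists were not (0.154 to 0.668).

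Against ketanserin alone at 1 mg/kg, the combination had more Dcun1d2, at 3.34 ± 1.48 against 0.177 ± 0.126 CPM (SD, n = 4; log2 fold change 4.19, SE 1.04), Map7 (0.50) and Kdelc1 (0.67). It had less Tsc22d4 (-2.40), Rgs20, a regulator of G protein signalling (-0.62), and Il17ra (-0.52). None passed. edgeR called 0 genes and 508 had an unadjusted p under 0.05, and DESeq2 and a fit of only these groups called 0. Myelin genes were higher in 18 of 18 members (median 0.27, camera adjusted p = 0.00943), with Opalin (0.52), Mobp (0.62) and Mal (0.50), at 0.18, 0.27 and 0.15 without replicate 2 of the combination. Heat shock genes were lower in 12 of 14 (-0.11, adjusted p = 0.00943), ribosomal protein genes in 66 of 82 (-0.09, adjusted p = 0.00943) and respiration genes in 68 of 82 (-0.09, adjusted p = 0.0410), with Sdf2l1 at -0.60 and Rps2 at -0.22. Without replicate 4 of ketanserin alone the last 2 medians were -0.20 and -0.21 (4.10e-07 and 1.39e-06). All 4 lists had an adjusted p of 0.970 with an estimated correlation. Of the 4, only the myelin call was kept with surrogate variables (0.000310; the others 0.151 to 0.902).

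Against ketanserin alone at 3 mg/kg, LOC100911575 (3.25, SE 0.617) was at 59.6 ± 18.6 against 6.32 ± 6.49 CPM (SD, n = 4) and Faah record ENSRNOG00000045949 (3.31, SE 0.811) at 14.7 ± 10.1 against 1.47 ± 0.147. Plin3, a lipid droplet protein (1.13; 0.69 without the distant library), was at 4.92 ± 2.62 against 2.24 ± 0.534. Hnrnpa0, an RNA-binding protein (-0.34), was at 137 ± 5.77 against 173 ± 10.4 CPM, and LOC100911319 (-1.53; -0.95 without replicate 2 of ketanserin alone) and Dock8 (-0.98) were also lower. None of these passed in edgeR, which called 0 genes (594 at an unadjusted p under 0.05). DESeq2 called 5, LOC100911575, Faah, Rpl35a and 2 unnamed transcripts, and a fit of only these groups called 1 unnamed transcript. Without replicate 3 of ketanserin alone, the highest of its group, LOC100911575 was called (adjusted p = 0.0128). Blood genes were higher in 6 of 6 members (median 0.55), with Slc4a1 at 0.88 and Alas2 at 0.72 (0.27 and 0.26 without the distant library), and ribosomal protein genes in 68 of 82 (0.12), with Rpl34 at 0.35 (0.22 without replicate 3 of ketanserin alone, 0.21 without replicate 2 of the combination). The blood and ribosomal medians were 0.34 and 0.24 without the distant library (0.0190 and 2.72e-08). Both lists had a camera adjusted p of 0.00260 and an adjusted p of 0.931 with an estimated correlation. The blood call was lost with surrogate variables (0.0644), the ribosomal one without replicate 3 of ketanserin alone (0.585).

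The interaction, which asks whether the combination departs from the sum of the single drugs, was tested at each dose. At 1 mg/kg it was highest by p for Pla2g4e (0.67, SE 0.158), LOC100912534 (6.81, SE 1.64; 4.38 without replicate 1 of the combination, at 9.0 CPM, and 4.96 without vehicle replicate 4, at 4.80) and Taz, the tafazzin gene of cardiolipin remodelling (0.52). It was lowest for Zfpm1, a cofactor of GATA factors (-0.78), C1ql2 (-2.12) and Fscn1, an actin-bundling protein (-0.51). At 3 mg/kg it was highest for Myom2, a muscle M-band protein (2.40, SE 0.554), Serhl2 (1.81) and Epcam (2.91). There it was lowest for C2cd4c (-0.82, SE 0.180), Gorasp2, a Golgi stacking protein (-0.87), and Grcc10 (-6.61, or -1.59 without the psilocybin library at 75.4 CPM). None passed. In edgeR 0 genes were called at either dose, with 712 and 557 at an unadjusted p under 0.05. DESeq2 and fits of only the groups compared called 0. Without replicate 1 of psilocybin alone C1ql2 was called at 1 mg/kg (adjusted p = 0.0459).

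Immediate early genes had a negative interaction in 24 of 30 members at both doses. Medians were -0.19 at 1 and -0.26 at 3 mg/kg (camera adjusted p = 0.0229 and 0.0241). With an estimated correlation the adjusted p was 0.964 and 0.924. The list score was lowest in vehicle, which enters both. The combination scored above psilocybin alone at 1 and below it at 3 mg/kg, with neither called. Fosb was at -0.88 and -0.83 (the latter -0.44 without replicate 2 of ketanserin alone), Egr4 at -0.62 at 1 mg/kg, and Csrnp1 at -0.88 and Maff at -1.63 at 3 mg/kg. At 1 mg/kg the interaction was also negative for heat shock genes in 14 of 14 members (-0.22, adjusted p = 0.000235). So it was for ribosomal protein genes (-0.18, adjusted p = 0.000235) and respiration genes (-0.18, adjusted p = 0.000791), each in 70 of 82 members, with medians of -0.28 and -0.30 without replicate 4 of ketanserin alone. Sdf2l1 was at -0.89 and Rpl32 at -0.91. At 3 mg/kg it was positive for myelin genes in 16 of 18 (0.29, 0.0241), with Enpp2 at 0.46 and Gjb1 at 0.79. Surrogate variables ended the immediate early, ribosomal and respiration calls at 1 mg/kg (adjusted p of 0.0750 to 0.944), and without the distant library the myelin call at 3 mg/kg was lost (0.119). Both 3 mg/kg calls were lost without replicate 1 of psilocybin alone (0.113 and 0.0790). The immediate early calls were lost without replicate 4 of ketanserin alone at 1 mg/kg (0.274) and its replicate 3 at 3 mg/kg (0.0511).

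Between the doses of psilocybin, Palmd (palmdelphin) was higher at 3 mg/kg (20.4 ± 0.503 against 13.7 ± 0.538 CPM, SD, n = 4; log2 fold change 0.57, SE 0.104, adjusted p = 0.109), as were Adprhl1 (1.71) and Grcc10 (4.74, or -0.30 without its library at 75.4 CPM). Syt12 (65.1 ± 0.672 against 87.9 ± 6.47 CPM, -0.43, SE 0.0801, adjusted p = 0.109), Nefl, the light neurofilament chain (475 ± 29.5 against 657 ± 79.3, -0.47, SE 0.0926, adjusted p = 0.169), and Galnt9, a glycosyltransferase (-0.41, SE 0.0876), were lower. edgeR called 0 genes, and 564 had an unadjusted p under 0.05. A fit of only these groups called 0, and DESeq2 called 6, Nefl, Galnt9, Syt12, Scn4b, Palmd and Mrpl36. With surrogate variables edgeR called 12 genes, among them Galnt9, Syt12, Nefl, Palmd and the complexin gene Cplx1. Without replicate 1 of psilocybin at 1 mg/kg it called 4, Nefl, Calb1, C1ql2 and an unnamed transcript.

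Myelin genes were lower at 3 than at 1 mg/kg of psilocybin in 18 of 18 members, with a median log2 fold change of -0.62 (camera adjusted p = 1.91e-14; adjusted p = 0.382 with an estimated correlation), including Ugt8 (-0.92), Gjb1 (-0.99) and Cldn11 (-0.71). The list score was -0.306 ± 0.471 at 3 mg/kg and 0.289 ± 0.540 at 1 mg/kg (SD, n = 4). The difference of -0.595 did not pass a two-sided exact permutation test (p = 0.143, and 1.00 after Benjamini-Hochberg adjustment over 27 lists). Ribosomal protein genes were higher in 69 of 82 (0.15, camera adjusted p = 0.000631; adjusted p = 0.938 with an estimated correlation), with Rps10 at 0.28 and Rpl30 at 0.59 (0.96 and 0.39 without replicates 2 and 3 of 1 mg/kg). The ribosomal call was lost (0.730) and its median turned to -0.04 without replicate 1 of 3 mg/kg (score 0.693 against 0.0434 to 0.119), where the myelin call was kept (-0.49, 7.25e-10). Calb1 of the upper layer list (0.41) and Hapln4 (-0.72) and Mmp9 (-1.65) of the perineuronal net list passed adjusted over the list alone, in lists that were not called.

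**Figure D3:**
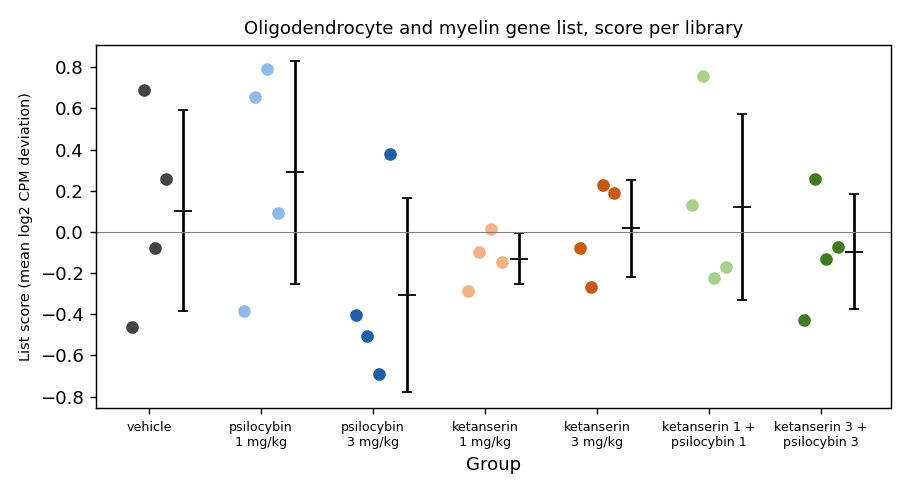
Myelin and mature oligodendrocyte list score (mean deviation of log2 CPM from the mean over all libraries) on the y axis, by treatment group on the x axis, with 1 point per library and bars for the mean ± SD of 4 libraries. The groups overlap, with means from -0.306 after psilocybin at 3 mg/kg to 0.289 after psilocybin at 1 mg/kg.

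Between the doses of ketanserin, Dcun1d2 (3.67, SE 1.04), Pip5kl1 (1.10) and LOC100910577 (1.03) were higher at 3 mg/kg. LOC100911575 (-2.78, SE 0.607; 6.32 ± 6.49 against 43.2 ± 11.6 CPM, SD, n = 4), Proser3 (-0.47) and Faah record ENSRNOG00000045949 (-3.16; 1.47 ± 0.147 against 13.2 ± 12.5 CPM) were lower. None passed, with 0 genes called by edgeR, 286 at an unadjusted p under 0.05, and 0 called by DESeq2 and by a fit of only these groups. Deep layer neuron markers were higher in 12 of 13 members (median 0.23, camera adjusted p = 0.0135), with Ntsr1 at 0.93 (0.50 without replicate 2 of 3 mg/kg) and Syt6 at 0.32 (0.21 without replicate 1 of 1 mg/kg). Blood genes were lower in 6 of 6 (-0.39, adjusted p = 0.0258), ribosomal protein genes in 75 of 82 (-0.16, adjusted p = 2.18e-07) and respiration genes in 75 of 82 (-0.16, adjusted p = 1.06e-06). Slc4a1 was at -0.61, Rpl17 at -0.73 and Ndufaf5 at -0.30. The 4 lists had an adjusted p of 0.929 with an estimated correlation. The ribosomal score was -0.331 in replicate 4 of ketanserin at 1 mg/kg against 0.0957 to 0.147 in its other 3 libraries. Without it the deep layer and blood calls were lost (0.261 and 0.461), Slc4a1 was at -0.23, and the ribosomal and respiration medians were -0.27 and -0.28 (1.43e-13 each). Without replicate 3 of ketanserin at 3 mg/kg the ribosomal and respiration calls were lost (0.0682 and 0.164). Surrogate variables ended the blood call (0.0909).

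With both doses of psilocybin pooled against vehicle, RragB (1.83, SE 0.440), Rmnd5b (3.62, SE 0.995) and Fam111a (5.11, SE 1.64; 2.84 without the 1 mg/kg library at 43.7 CPM) were higher. Pla2g4e (-0.39, SE 0.0954), Klhl20, a ubiquitin ligase adaptor (-0.41), and Dennd3, an activator of a Rab GTPase (-0.67), were lower, and none passed. edgeR called 0 genes, 341 had an unadjusted p under 0.05, and DESeq2 and a fit of only these groups called 0. Immediate early genes were higher as a list in 24 of 30 members (median 0.17, camera adjusted p = 0.000196), heat shock genes in 12 of 14 (0.07, adjusted p = 0.0465) and innate immune and interferon genes in 12 of 17 (0.09, adjusted p = 0.0490). So were ribosomal protein genes in 76 of 82 (0.17, adjusted p = 3.83e-09) and respiration genes in 75 of 82 (0.12, adjusted p = 5.19e-05). Fosb was at 0.65, Hsp90aa1 at 0.39, Psmb9 at 0.48, Mx1 at 0.68 (0.44 without vehicle replicate 4), Rpl19 at 0.22 and Atp5f1 at 1.05, or 0.36 without replicate 4 of 3 mg/kg (12.1 CPM against 0.833 to 2.63). The 5 lists had an adjusted p of 0.911 with an estimated correlation. Surrogate variables ended the heat shock and respiration calls (0.384 and 0.590), and the heat shock call was also lost without the distant library (0.0566). The heat shock, innate immune and respiration calls were lost (0.265, 0.0878 and 0.168), and the immediate early and ribosomal medians were 0.11 and 0.07 (0.000989 and 0.000506), without replicate 1 of 3 mg/kg (heat shock score 0.294 against -0.113 to -0.0504, ribosomal 0.693 against 0.0434 to 0.119).

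With both doses of ketanserin pooled, LOC100911575 (2.40, SE 0.580), Dusp6 (0.46, SE 0.120) and Rmnd5b (3.56) were higher than in vehicle. Slfn13 (-1.01, SE 0.239), Serhl2 (-1.06) and Faah record ENSRNOG00000045949 (-2.33, SE 0.604) were lower. None passed in edgeR, which called 0 genes with 366 at an unadjusted p under 0.05. DESeq2 and a fit of only these groups called 0. Immediate early genes were higher in 24 of 30 members (median 0.19, camera adjusted p = 1.75e-09; adjusted p = 0.121 with an estimated correlation), with Fosb (0.69), Csrnp1 (0.52) and Nr4a1 (0.45), and 1 member, Dusp6, passed adjusted over the list alone. Late activity genes were higher in 14 of 19 (0.07, adjusted p = 0.00662; adjusted p = 0.347 with an estimated correlation), with Nptx2 at 0.21. Synaptic structure genes were higher in 17 of 29 (0.03, adjusted p = 0.00258), with Dlg4 at 0.20, and meninges and fibroblast markers lower in 13 of 13 (-0.23, adjusted p = 0.00335), with Col3a1 at -0.65. Both had an adjusted p of 0.504 with an estimated correlation, and without replicate 4 of 1 mg/kg the synaptic list was still called higher (0.0407) at a mean of -0.08. Myelin genes were lower in 18 of 18 (-0.21, adjusted p = 0.0315; adjusted p = 0.961 with an estimated correlation), with Aspa at -0.39 (-0.13 without vehicle replicate 2). Surrogate variables ended the late activity and myelin calls (0.0901 and 0.0552), and the myelin call was also lost without the distant library (0.0625).

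With both doses of the combination pooled, LOC100911575 rose by a log2 fold change of 3.82 against vehicle (SE 0.614, edgeR adjusted p = 0.0352). It was the only gene that edgeR called, with 313 at an unadjusted p under 0.05. Dcun1d2 (3.60), Rmnd5b (3.61), Tsr2 (-0.62), Nhp2, a small nucleolar RNA protein (-4.74, through 1 vehicle library at 52.5 CPM and -0.02 without it; also at 2 levels between animals), and B3gnt1 (-1.79, through 1 vehicle library at 6.67 CPM and -0.34 without it) followed and did not pass. DESeq2 called 4 genes, LOC100911575, Rmnd5b, Dcun1d2 and Rpl35a, and a fit of only these groups called 0. In the 12 fits with 1 library left out, LOC100911575 stayed called only without replicate 3 of the 1 mg/kg combination (adjusted p = 0.00135; 0.0550 to 0.366 in the other 11, with a log2 fold change of 3.65 to 3.98). It was not called without a filter (0.154) or with surrogate variables (0.232), at 3.83 and 3.85. Immediate early genes were higher in 23 of 30 members (median 0.21, camera adjusted p = 9.47e-06; adjusted p = 0.580 with an estimated correlation), with Arc at 1.14 and Junb at 0.60. Deep layer markers were higher in 11 of 13 (0.18, 0.0368) and blood genes in 5 of 6 (0.26, 0.0165), both at an adjusted p of 0.610 with an estimated correlation, with Foxp2 at 0.66 and Alas2 at 0.58 (1.02 without vehicle replicate 2, 0.35 without the distant library). Respiration genes were lower in 72 of 82 (-0.11, adjusted p = 0.0165; adjusted p = 0.864 with an estimated correlation), with Uqcrh at -0.21. The blood call was lost with surrogate variables (0.0612), and the respiration call with them (0.811) and without the distant library (0.839).

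The immediate early score, averaged over the 30 genes of that list in each library, was -0.191 ± 0.120 in vehicle (SD, n = 4). It was 0.0291 ± 0.0339 and -0.0109 ± 0.179 after psilocybin, 0.124 ± 0.134 and 0.0142 ± 0.257 after ketanserin, and 0.120 ± 0.101 and -0.0850 ± 0.240 after the combinations, at 1 and 3 mg/kg. At 1 mg/kg all 3 treated groups stood above all 4 vehicle libraries. The two-sided exact permutation p was 0.0286, the smallest that 70 splits allow, and 0.771 after adjustment over the 27 lists. At 3 mg/kg the exact permutation p was 0.200 for psilocybin, 0.171 for ketanserin and 0.514 for the combination.

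**Figure D4:**
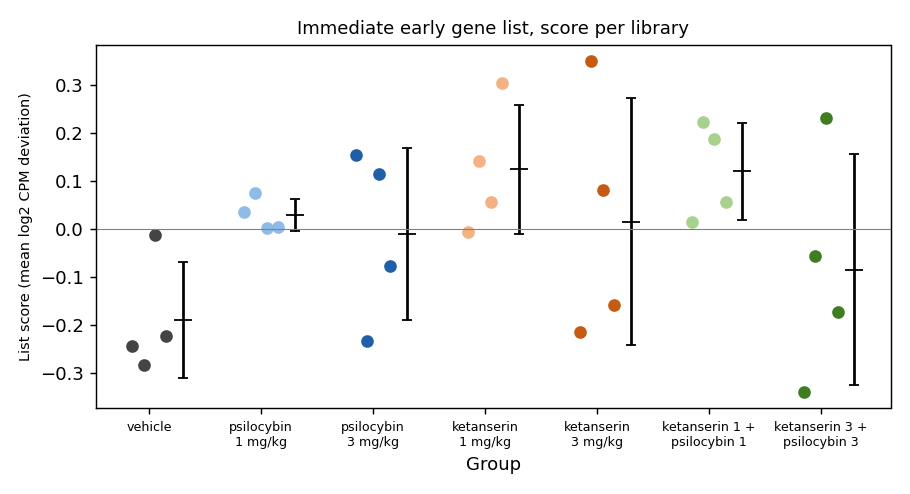
Immediate early gene list score (mean deviation of log2 CPM from the mean over all libraries) on the y axis, by treatment group on the x axis, with 1 point per library and bars for the mean ± SD of 4 libraries. Vehicle libraries lie at -0.283 to -0.0138, and the means of the 6 treated groups lie between -0.0850 and 0.124 with wide overlap at 3 mg/kg.

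Across the 7 groups the edgeR test for any difference called 3 genes, with 387 at an unadjusted p under 0.05. The 3 were LOC100911575 (adjusted p = 0.00179), Grcc10 (0.0333) and Mrpl36 (0.0411), and C1ql2 (0.179), Syt12 (0.216), Tsc22d4, Dcun1d2 and LOC100911713 (0.917 each) did not pass. Group means ran from 3.12 to 59.6 CPM for LOC100911575, from 0.321 to 5.93 for Mrpl36 and from 0.199 to 19.3 for Grcc10, whose highest mean came from 1 library. DESeq2 called 15 genes, LOC100911575 and Mrpl36 among them but not Grcc10. Grcc10 was also not called without a low-count filter (2 genes) or with surrogate variables, where Syt12 was. In the 28 fits with 1 library left out, 1 to 3 genes were called, with LOC100911575 called in all 28, Grcc10 in 6 and Mrpl36 in 4.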

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

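The list tests without 1 library that stood apart and the tests of the spread of the immediate early list between animals, of lower depth, of a transcript length trend and of near-identical copies were chosen after the results were seen.

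Camera with a preset correlation called immediate early genes higher than vehicle in 6 of 6 treated groups, a pattern picked out of 27 lists after it was seen. Chance cannot be excluded for a list picked in this way, since some list was called in 6 groups in 22 of 100 splits of the 28 libraries (real value 6, highest other 6), although this list reached 6 only in the real split, 1 of 100 (highest other 4). A gradient unrelated to group stays open. Surrogate variables kept 5 of 6 calls, but camera made a median of 78 list calls in other splits. An estimated correlation kept 0 of 6 (adjusted p of 0.109 to 0.864). A single vehicle library and the spread of the list between animals cannot be told apart from a drug effect, because 4 to 6 groups were called without 1 vehicle library (4 without replicate 2) and because the score differed by 0.222 between vehicle and all treated libraries with an exact permutation p of 0.0193 (20475 splits; 0.521 after adjustment over 27 lists). The call at 3 mg/kg of psilocybin was lost without its replicate 1 (adjusted p = 0.155).

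Replicate 4 of the 3 mg/kg combination lay far from the other 27 libraries. Lower depth is argued against, because the others thinned to its total of 12783067 had 15571 to 16853 genes and transcripts at 0, against its 19602. Tissue of another region is argued against for the 4 regions with a marker list, whose scores differed from the median of the others by 0.0023 for olfactory bulb, -0.404 for striatum, -0.913 for choroid plexus and ependyma and -0.331 for meninges. A transcript length trend is argued against as the whole cause, since its Spearman rho across genes, which are not independent replicates, was 0.284 and that of libraries that did not lie apart ran from -0.341 to 0.282. RNA quality was not measured here, no biological explanation was tested, and the cause stays open.

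Among the tested genes 33, 3 of them unnamed transcripts, sat at 2 levels between animals. Of these, 24.2% shared their symbol with another gene record against 2.04% of the other tested genes, a ratio of 11.9, so reads shared between near-identical copies may be part of the cause. Variants carried by some animals of this outbred stock may be another part, since pairs under 5 Mb apart had a median absolute correlation of 0.316 (15 pairs) against 0.129 for pairs on different chromosomes (486 pairs), a difference of 0.186, though many near pairs lie on chromosome 20 and are not independent. Treatment cannot be told apart from these, because 20.3% of 10000 relabellings had as many such genes differing between groups as the 3 observed (median 1, highest 8), and missing a 5% bound excludes nothing, so the bound set beforehand was too strict. LOC100911575 was not among the 33 (largest gap 1.04 log2 units). Its libraries lay at 2.10 to 5.61 or 26.6 to 87.3 CPM, except at 11.7 and 16. A variant there and treatment cannot be told apart. Its median absolute correlation with 139 neighbours under 5 Mb away (0.152, percentile 51.3 of random sets) cannot show a variant of this gene alone.

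Counts of called genes were set against 100 splits of the 28 libraries, the real one included. Where the real count was 0 all 100 splits reach it by construction, so they decide nothing, and chance cannot be excluded for the 3 comparisons with calls. Where it was 0, the highest other counts were 6636, 6192 and 6376 for psilocybin at 1 mg/kg, at 3 mg/kg and pooled against vehicle, and 1, 1 and 2 for ketanserin. They were 5114 for the 3 mg/kg combination against psilocybin alone and 0 to 2726 elsewhere. The 3 mg/kg combination against vehicle had 1 real call and as many in 5 of 100 splits (highest other 1). The pooled combination had 1, reached by 13 (highest other 1052), and the test among 7 groups had 3, reached by 17 (highest other 3137). Splits calling so many genes point to a structure besides the groups. PC1 mostly fell as the gene length rho rose, from 72.0 and -0.323 to -38.3 and 0.283 (distant library aside). Its role in ribosomal and respiration calls was not tested. For the list tests the real count was 71, reached by 63 of 100 splits (highest other 123).

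Lists called in the tests of a difference between effects had these median log2 values. At 1 mg/kg the interaction was -0.19 for immediate early, -0.22 for heat shock, -0.18 for ribosomal and -0.18 for respiration genes, and at 3 mg/kg -0.26 for immediate early and 0.29 for myelin genes. Between psilocybin doses myelin genes were at -0.62 and ribosomal genes at 0.15. Between ketanserin doses deep layer markers were at 0.23, blood genes at -0.39, ribosomal genes at -0.16 and respiration genes at -0.16. With an estimated correlation none of these 12 was called (adjusted p of 0.382 to 0.964). Surrogate variables ended the calls of immediate early, ribosomal and respiration genes at 1 mg/kg and of blood genes. With 1 library that stood apart left out, calls were lost for immediate early genes at both doses (0.0511 to 0.274), myelin genes at 3 mg/kg (0.0790 and 0.119), ribosomal genes between psilocybin doses (0.730) and all 4 lists between ketanserin doses (0.0682 to 0.461).

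In 53 of 588 sets of 4 libraries examined, 1 library stood far from the other 3, by a test that chance passes in about 1 in 20 sets of independent normal values. Many of these genes were named for a small p, so the sets are not a random sample. The values of 52 follow, in CPM for genes, each against the range of the other 3. Of the vehicle libraries, replicate 2 differed in Sh2b3 (22.5 against 29.1 to 30.1), Yars2 (23.8 against 16 to 17.3), Nhp2 (52.5 against 0.372 to 0.744), B3gnt1 (6.67 against 0.620 to 0.960) and Hbb (642 against 272 to 329). It also differed in Hba1 (1284 against 513 to 619) and Crym (341 against 192 to 207). Replicate 3 was apart in the percent of counts in unnamed transcripts (2.30 against 2.18 to 2.19). Replicate 4 lay apart for LOC100912534 (4.80 against 0.372 to 0.473). With psilocybin at 1 mg/kg, replicate 1 differed in Il6r (7.33 against 5.77 to 5.99), Fam111a (43.7 against 0.337 to 0.686) and Htr2a (34.1 against 27.5 to 28.2). Replicate 3 differed in Ndufa1 (54.3 against 0 to 0.549). Replicate 4 was apart in Hspd1 (166 against 177 to 178). At 3 mg/kg psilocybin, replicate 1 differed in the heat shock score (0.294 against -0.113 to -0.0504), the ribosomal score (0.693 against 0.0434 to 0.119), the upper layer score (-0.441 against -0.0169 to 0.0669), Ndufa2 (115 against 66.4 to 72.6) and Ndufb6 (140 against 82.9 to 92.0). Replicate 2 stood apart for Ndufa1 (52.6 against 0 to 0.995). Replicate 3 differed in Rpl35a ENSRNOG00000047557 (0.0694 against 0). Replicate 4 was apart in Grcc10 (75.4 against 0.0694 to 0.995), Enpp2 (48.6 against 39.3 to 40.4) and Atp5f1 (12.1 against 0.833 to 2.63). With ketanserin at 1 mg/kg, replicate 1 differed in Rgs20 (35.4 against 32.9 to 33.3). Replicate 3 stood apart for Pla2g4e (19.4 against 20.9 to 21) and Rmnd5b (14 against 1.1 to 3.19). Replicate 4 differed in Spearman's rho across genes of deviation with gene length (0.206 against -0.189 to -0.176), the ribosomal score (-0.331 against 0.0957 to 0.147) and the respiration score (-0.352 against 0.108 to 0.155). At 3 mg/kg ketanserin, replicate 1 differed in Rpl7a ENSRNOG00000049097 (10.2 against 8.36 to 8.63). Replicate 2 lay apart for LOC100911319 (4.30 against 1.31 to 1.76) and Foxc1 (6.51 against 10.6 to 10.8). Replicate 3 stood apart for the deep layer score (-0.104 against 0.206 to 0.225), LOC100911575 (16 against 2.50 to 3.52) and Rpl8 (35.5 against 6.39 to 10.4). In the 1 mg/kg combination, replicate 1 differed in LOC100912534 (9.0 against 0.171 to 0.834). Replicate 2 was apart in Rmnd5b (12.2 against 5.01 to 5.48) and Il17ra (42.6 against 27.7 to 29.4). Replicate 3 lay apart for Fscn1 (147 against 124 to 128) and Rpl35a ENSRNOG00000047557 (0.228 against 0). Replicate 4 stood apart for Dusp6 (36.7 against 29.0 to 30). In the 3 mg/kg combination, replicate 2 differed in the percent of counts in the 10 highest genes (10.5 against 7.93 to 8.26), LOC100911575 (87.3 against 46.9 to 52.6) and Atp5f1 (0.541 against 1.42 to 1.55). Replicate 3 was apart in Dock8 (3.47 against 1.96 to 2.16) and Ndufa1 (14.7 against 0.0762 to 0.406). Replicate 4 lay apart for the percent of counts in unnamed transcripts (4.46 against 2.06 to 2.29), Epcam (4.42 against 0.879 to 1.05), Tsc22d4 (14.5 against 2.16 to 3.29) and Plin3 (8.84 against 3.41 to 3.72). It also differed in Shank1 (3385 against 1287 to 1352).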

How the results depend on the processing

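The list tests without 1 library that stood apart, and the gene tests without replicate 4 of the 3 mg/kg combination in comparisons that do not hold it, were chosen after the data had been examined. No paired analysis was possible because the labels number no replicates. Depth limits the precision together with the spread between animals. The median half-width of a 95% interval was near 0.438 log2 units in pairwise comparisons. Of 416 results for named genes, 416 kept their direction and their side of the threshold with RLE size factors, 414 without a low-count filter, 399 with DESeq2, and 404 with surrogate variables. With DESeq2 17 gained a call, and without a filter 2 lost it. Surrogate variables gave 4 gains, 2 losses and 6 reversals, and fits of only the groups compared kept 385, with 6, 1 and 1, and gave no value for the rest. Fits with 1 library left out kept 4212 results for genes and gave 6 gains, 16 losses and 42 reversals. Of 71 called lists, surrogate variables kept 40 (25 lost, 6 with camera's direction turned) and omitting the distant library 63 (7 lost, 1 turned). Without replicate 1 of psilocybin at 3 mg/kg 57 were also called (12 lost, 2 turned), without replicate 4 of ketanserin at 1 mg/kg 65 (6 lost) and without replicate 3 of ketanserin at 3 mg/kg 62 (9 lost).

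Camera with an estimated correlation and fry each called 0 lists, where 71 were called with the preset correlation. RLE size factors moved no count of genes. Without a low-count filter, when 26522 in place of 17404 genes were tested, LOC100911575 was not called in the 3 mg/kg combination or the pooled combination, which each had 0 genes against vehicle in place of 1. It was called there among the 7 groups, where 2 genes passed in place of 3 and Grcc10 was lost. With surrogate variables both were again at 0, and psilocybin at 3 against 1 mg/kg had 12 in place of 0. DESeq2 called 3 genes for psilocybin at 1 mg/kg, and 1 for each ketanserin dose and the 1 mg/kg combination, against vehicle. It called 1 for the combination against psilocybin alone at each dose and 5 against ketanserin alone at 3 mg/kg. It called 6 between the psilocybin doses, 4 for the pooled combination and 15 among the 7 groups. Fits of only the groups compared called 1 gene for each psilocybin dose, and 2 and 1 for ketanserin at 1 and 3 mg/kg. They called 2 for the 1 mg/kg combination against vehicle, 1 for the 3 mg/kg combination against each drug alone, and 0 when pooled. Leaving out 1 library at a time gave counts of 0 to 1 for each combination against vehicle, the interaction at 1 mg/kg, the pooled combination, each combination against psilocybin alone and the 3 mg/kg combination against ketanserin alone. It gave 0 to 4 between the psilocybin doses, 1 to 3 among the 7 groups, and 0 to 0 in the other 9 comparisons. The cause was not tested for these changes.

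With surrogate variables the direction of camera's test turned for 6 called lists. The mean log2 fold change then was 0.035 for ribosomal genes in the 1 mg/kg combination against vehicle, 0.030 for respiration genes in the 3 mg/kg combination and 0.053 in the pooled combination. Against psilocybin alone at 3 mg/kg it was -0.15 for synaptic structure and -0.050 for respiration genes, and against ketanserin alone at 1 mg/kg -0.078 for ribosomal genes, the last 2 with the sign of the mean kept. Without each of the 4 libraries that stood apart the mean ran from -0.071 to 0.088 for respiration genes in the 3 mg/kg combination against vehicle, from 0.034 to 0.218 for respiration genes with psilocybin at 3 mg/kg and from -0.12 to 0.056 for ribosomal genes between psilocybin doses, with the test's direction turned in 1 fit each. Genes that reversed with surrogate variables were Htr2a with ketanserin at 1 mg/kg (-0.0062), at 3 mg/kg (-0.0013) and pooled (-0.0038), Htr2c for the combination against psilocybin alone at 1 mg/kg (0.0022), and Shank1 (-0.068) and Dlgap1 (-0.023) for the same contrast at 3 mg/kg. In a fit of only the groups compared Htr2a with ketanserin at 1 mg/kg was at -0.0058. None of these genes was called. The cause was not tested.

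Other reversals came with 1 library left out, in genes that no comparison called there, with ranges of log2 fold change as follows. For Htr2a they were -0.050 to 0.078 with psilocybin at 3 mg/kg, -0.17 to 0.094 with ketanserin at 1 mg/kg, -0.16 to 0.12 at 3 mg/kg and -0.080 to 0.076 pooled. They were -0.18 to 0.0015 with the 1 mg/kg combination, -0.18 to 0.11 and -0.26 to 0.017 for the combinations against ketanserin alone at 1 and 3 mg/kg, -0.26 to 0.016 for the interaction at 3 mg/kg and -0.15 to 0.19 between ketanserin doses. For Htr2c they were -0.083 to 0.27 with ketanserin at 1 mg/kg, -0.064 to 0.34 with the 3 mg/kg combination, -0.16 to 0.060 for the combination against psilocybin alone at 1 mg/kg, -0.29 to 0.057 for the interaction at 1 mg/kg and -0.19 to 0.076 between psilocybin doses. Ndufa1 ran from -0.47 to 5.51 with psilocybin at 1 mg/kg, -0.87 to 3.66 with the 3 mg/kg combination and -4.06 to 0.29 between ketanserin doses. Rpl35a ENSRNOG00000047557 ran from -7.94 to 2.84 for the combination against ketanserin alone at 1 mg/kg and from -8.36 to 0 between ketanserin doses, fitted values that are no bounds because libraries sat at 0. Grcc10 ran from -0.30 to 5.15 between psilocybin doses, Cldn11 from -0.44 to 0.017 with ketanserin pooled, and Shank1 from -0.057 to 0.57 for the combination against psilocybin alone at 3 mg/kg. The cause was not tested.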

Other observations

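Ndufa1, which encodes a subunit of mitochondrial complex I, was at 0.400 ± 0.277 CPM in vehicle (SD, n = 4) and at 18.3 to 44.6 CPM in all 4 libraries of the 1 mg/kg combination, with a mean of 32.5. Psilocybin at 1 mg/kg had 13.8 ± 27 CPM with 1 library at 54.3, psilocybin at 3 mg/kg 13.5 ± 26.1 with 1 at 52.6, ketanserin at 1 mg/kg 3.94 ± 7.36 with 1 at 15, and the 3 mg/kg combination 3.84 ± 7.25 with 1 at 14.7. Ketanserin at 3 mg/kg had 0.317 ± 0.191. A record of the ribosomal protein gene Rpl35a, ENSRNOG00000047557, was at 0 in all libraries of vehicle and of ketanserin at 3 mg/kg, and at 2.40 ± 2.84 CPM with psilocybin at 1 mg/kg, 1.98 ± 3.96 with ketanserin at 1 mg/kg and 3.18 ± 3.71 with the 3 mg/kg combination. In the remaining groups Rpl35a was at 0 in 3 of 4 libraries. Both were among the 33 genes at 2 levels between animals, and neither passed in the edgeR fit of all groups. Ndufa1 was called for the 1 mg/kg combination against vehicle in a fit of only these groups (adjusted p = 0.00472), and DESeq2 called Rpl35a in the pooled combination against vehicle (0.0426) and the 3 mg/kg combination against ketanserin alone (0.0378). Fitted folds of Rpl35a are no bounds, since libraries were at 0.

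Of 459 list tests with the preset correlation, 71 were called, and 13 of the 27 lists were called in 0 of the 17 comparisons. Serotonin receptors came closest with ketanserin at 3 mg/kg, where 8 of 9 members were above vehicle (median log2 fold change 0.20, camera adjusted p = 0.0629). Choroid plexus and ependyma markers had their smallest adjusted p with ketanserin at 1 mg/kg (0.0643). For the oligodendrocyte precursor and the perineuronal net and matrix lists it was 0.0963, both between the psilocybin doses. Circadian clock genes were higher in the 1 mg/kg combination than after psilocybin alone in 14 of 17 (0.14, adjusted p = 0.105), and GABA signalling genes in the 3 mg/kg combination than after psilocybin alone in 16 of 18 (0.12, adjusted p = 0.123). The smallest adjusted p was 0.156 for astrocyte markers, 0.232 for striatum markers, 0.235 for other ketanserin targets, 0.290 for glucocorticoid response genes, 0.319 for endothelial and mural markers, 0.338 for interneuron markers and 0.841 for olfactory bulb markers. Mmp9, a matrix protease of the perineuronal net list, was at -1.59 in the 1 mg/kg combination against psilocybin alone and passed adjusted over the list alone, but not over all genes.

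Fold changes against the shared vehicle libraries correlated across genes, which are not independent replicates, at 0.268 to 0.510 in the 6 pairs of treated groups compared. Simulated unchanged groups set against shared controls (10 simulations) gave 0.500, and the observed values were -0.129 to -0.0822 when the vehicle libraries were split between the groups. The covariance was 0.0387 to 0.0557 against a simulated 0.0713, so no covariance exceeded the simulated one, while of the correlations only that of the ketanserin doses (0.510) did.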
